A study of Mus musculus with 6 samples.

How the data were processed

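Flash-frozen lung tumors and normal lung from separate mice were used, with DNA and RNA taken from the same lysate, poly(A) selection and an NEBNext Ultra II library, per the labels' protocols. The submitters' processing notes name Trim Galore, Trimmomatic 0.36, STAR 2.5.4a, DESeq2 1.22.2, R 3.5.1 and the mouse build mm9, with no role or order. The deposited values are raw gene counts made by the authors with TPMCalculator, per the labels, whose strand setting and annotation are not given in the sources used here. The deposited counts were whole numbers for 22477 gene symbols, of which 645 were 0 in every library. Of the counts from 1 to 10, 61.2% were even, and the 14 largest values in the table were all multiples of 10. Poly(A) selection disfavors RNAs without a tail, so their counts depend on how complete the selection was. Reads of near-identical genes and of genes that overlap on either strand cannot be told apart in these counts.

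Samples were grouped by the tissue type in the labels, as 2 normal and 4 tumor libraries in 1 batch. No replicate number is shared between the groups, and each library names its own mouse. Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after its default filter by group (minimum count 10, minimum total 15) and TMM scaling, with tissue as the only term. P-values were adjusted by Benjamini-Hochberg over the 18027 genes kept, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM were computed on TMM-scaled library sizes, and log2 CPM use a prior count of 2. The common biological coefficient of variation was 0.433. The 2 normal libraries differed by more than sampling noise, as did every pair of tumors.

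The 36 gene lists held 722 entries and were written before the data were examined, as were the naming rule, the tests and the alternatives, except where a choice is said to be later. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 36 lists, and again with an estimated correlation and with fry, which asks only whether a list's genes move on balance one way. Camera called 29 lists. With an estimated correlation it called 0, with 5 lists at an unadjusted p under 0.05, and fry called 32. Lists with an estimate near or below 0.01 also lost their call there, so such a miss is not by itself evidence against a list. The naming rule took 17 genes of the study question, the 8 genes of highest and the 8 of lowest log2 fold change that passed the test, had a mean log2 CPM of at least 5 and had every tumor on the same side of both normal libraries, and up to 4 members per direction of each list by smallest p. It names 195 genes, of which the text gives a part, and 2 of its genes are not reported here. Epcam, Sftpc, Krt4, Krt13, Acta1, Ckm, Xist, the Y-linked genes and the 3 RNAs without a tail in the opening of the results were chosen after their values were seen.

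On simulated counts with the means, spreads and library sizes of the real data, the test recovered 4.0% of 50 genes changed 2-fold, 49.0% of 49 changed 4-fold, 88.0% of 50 changed 16-fold and 91.1% of 45 changed 64-fold, and called 4 of 17579 unchanged genes. That simulation changed 200 genes only, so its threshold was stricter than where most genes change. A first version, with 2-fold and 4-fold changes only, missed its own recovery limit. The fold sizes were then widened and that limit was replaced. A simulated list shifted 2-fold was called, and 0 of 35 unchanged lists were. The simulation did not carry over the correlation between genes of a list. In the real data its estimate ran from -0.0787 for the Schwann cell list to 0.745 for the epithelial list. The unchanged lists therefore cannot show how often camera with a preset correlation calls correlated lists wrongly. Alternatives were RLE, upper quartile and no composition scaling, no filter, a stricter filter of at least 1 CPM in every library of a group, DESeq2 1.42.0, limma voom, and leaving out each library in turn. Removal of small non-coding RNA, Rn45s and histone rows was added after the data were seen. Gene names and RNA classes came from RefSeq and GENCODE on GRCm38, where 21149 symbols of the table had a RefSeq match. No coordinates are printed because that build differs from mm9. Overlaps of genes stated in the results are those of GRCm38. Of the listed genes, 3 were matched by another symbol and 6, among them Atoh1 of the study question, were not analysed here.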

Results

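RNA was sequenced from 4 lung tumors and 2 samples of normal lung of the RPM mouse, a model of small cell lung cancer in which Cre recombinase deletes Rb1 and Trp53 and switches on a stabilized mutant form of Myc. Cre was delivered into the airway by an adenovirus whose CGRP promoter directs it to pulmonary neuroendocrine cells, and the labels list this virus for the normal samples as well. The libraries are called normal 1 and 2 and tumor 3, 4, 5 and 6 here, after the numbers in the sample titles, and each came from a different animal. The study as a whole concerned histone deacetylase inhibition and immunotherapy, but the labels give no treatment arm for these samples, so the only comparison made was tumor against normal lung. Total counts were 99122500 and 91049400 for normal 1 and 2, and 70817400, 54735400, 69616400 and 65859500 for tumors 3 to 6. Rn45s, Rpph1 and Rmrp, RNAs of the ribosome precursor, RNase P and RNase MRP that carry no poly(A) tail, together took 0.238% and 0.550% of the counts in normal 1 and 2 but 13.9%, 11.8%, 5.46% and 9.32% in tumors 3 to 6.

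Tumors and normal lung were far apart. Spearman correlations over the tested genes were 0.995 between the 2 normal libraries, 0.942 to 0.976 between tumors and 0.675 to 0.727 between a tumor and a normal library. Of 18027 genes tested, 5638 were higher and 5874 lower in tumors (edgeR quasi-likelihood test, adjusted p under 0.05), and 4628 and 5073 of these differed at least 2-fold. Without normal 1 the test called 7651 genes, 3373 of them higher, and without normal 2 it called 8091, 3740 of them higher. In both cases the lone normal library was assumed to vary as the tumors do.

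The genes engineered in the model were examined first. Myc was higher in every tumor, at 125 ± 55.3 CPM (SD, n = 4) against 13.1 ± 7.31 (n = 2), a log2 fold change of 3.25 ± 0.59 (SE, adjusted p = 0.00318), or 3.96 without normal 2. These counts do not separate the transgene from the native gene. Trp53 fell by 0.94 on the log2 scale (SE 0.27, adjusted p = 0.019), from 22.1 ± 0.747 to 11.5 ± 2.95 CPM, and was lower in 4 of 4 tumors. Rb1 stood at 62.6 ± 17.6 CPM in tumors and 77.8 ± 8.19 in normal lung, a difference that did not pass the test (adjusted p = 0.345). Only some exons of Rb1 and Trp53 are floxed, so counts over the whole gene are a weak check of their deletion. The Trp53 call was lost without normal 1 (log2 fold change -0.99) and without normal 2 (-0.92).

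**Figure D1:**
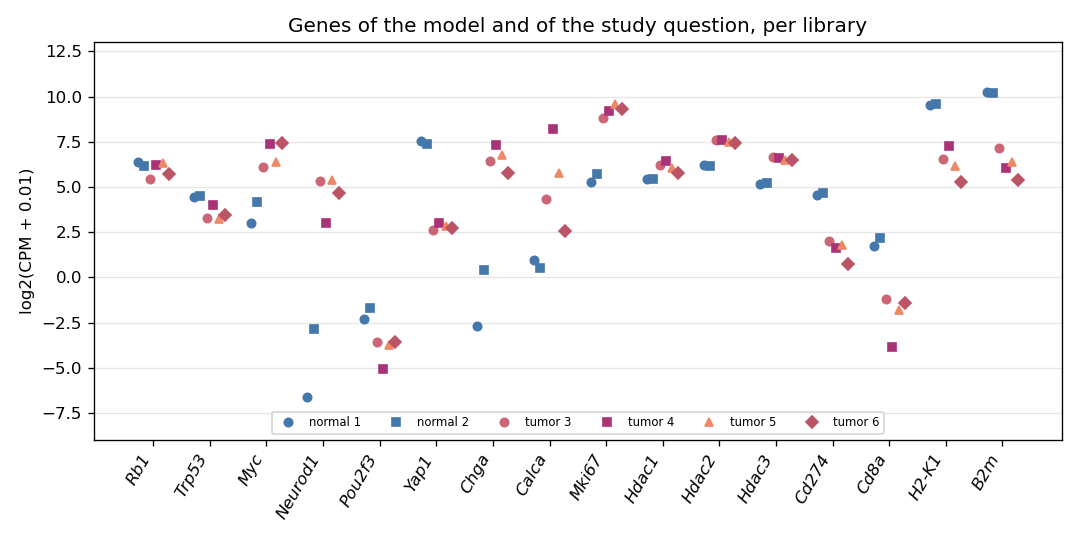
Level of genes of the model and of the study question in each library, as log2 of CPM plus an offset of 0.01, with 1 point per library and normal lung in blue. Neurod1 and Chga lay higher in all 4 tumors than in either normal library, and Yap1, Cd274, Cd8a, H2-K1 and B2m lay lower.

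The tumors expressed a neuroendocrine program that was close to absent from normal lung. Neurod1, a neurogenic transcription factor, rose from 0.0647 ± 0.0915 to 28.9 ± 15.6 CPM (log2 fold change 8.79 ± 1.43, adjusted p = 0.002). Its log2 fold change was 7.77 without normal 1. Without normal 2, which left 0 normal counts, it was 1004-fold higher against a floor of 3 counts over the group. Over all libraries, with 12 counts in normal 2, it was 441-fold higher. Such floors, and the intervals of count ratios below, cover counting error only and not the spread between animals. Of the 30 neuroendocrine genes, 28 rose, none fell and 2 did not pass, with a median log2 fold change of 6.31, or 5.65 without normal 1 and 7.01 without normal 2. Without tumor 4 the list had 1 member that fell, Grp, named after its values were seen. Among them were Chga, a core protein of dense granules, at 139-fold, Syp, a synaptic vesicle protein, at 15.0-fold, and Scg5, a chaperone of prohormone convertase, at 125-fold. The log2 fold change of Chga was 6.25 without normal 1 and 9.46 without normal 2. Calca, the gene of calcitonin and CGRP, rose by 5.79 ± 1.84, but its level ran from 5.86 CPM in tumor 6 to 293 in tumor 4, and its call was lost with limma voom (4.39), without normal 1 (6.04) and without normal 2 (5.55), while without tumor 4 the change was 4.0. Of 19 neuronal genes, 15 rose and none fell (median 5.88, or 5.76 with the 1 gene without normal counts at its bound), among them Dpysl5 at 6.47-fold and the kinesin gene Kif5c at 58.8-fold (log2 fold change 6.75 without normal 2). With genes lacking normal counts at their bound, the neuronal median was 4.75 without normal 1 and 6.75 without normal 2, and without tumor 5 Dpysl3, likewise named afterwards, fell. Both lists stood apart from other genes by camera with a preset correlation (adjusted p = 4.2e-09 and 0.000701), and neither did so with an estimated correlation (adjusted p = 0.278 and 0.383).

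Genes that oppose the neuroendocrine state were lower. All 18 tested members of the Notch and non-neuroendocrine list fell (median log2 fold change -3.30, adjusted p = 3.95e-07, or 0.248 with an estimated correlation). Several lists of normal lung cells fell by more, with medians of -5.11 for endothelium, -5.47 for alveolar type 1 and -3.47 for fibroblasts, against -3.01 for smooth muscle. Counts of whole tissue thus do not tell a change of cell state from fewer normal cells. Yap1, the Hippo pathway effector, was 25.4-fold lower at 6.93 ± 0.73 CPM against 176 ± 14.0, its partner Wwtr1 was 15.3-fold lower and the ephrin receptor gene Epha2 27.4-fold lower. Pou2f3, the regulator of tuft cells, was at most 0.302 CPM in any library (log2 fold change -2.02 ± 0.62), and its call was lost with DESeq2 (-2.01) and without normal 1 (-2.33), normal 2 (-1.69) or tumor 5 (-2.06). Of 10 tuft cell genes, 2 rose, 3 fell and 5 did not pass, and the list did not stand apart (adjusted p = 0.362). The eicosanoid genes Alox5ap and Ptgs1 were 8.68-fold and 11.8-fold lower, and Dclk1, a microtubule kinase, rose by 2.05 ± 0.47, though not past the threshold without normal 1 (2.02) or normal 2 (2.05). Chat, of acetylcholine synthesis, had 2 counts in normal lung and 124 in tumors, a ratio of 45.3 (95% interval 12.3 to 378, counting error only). Its call was lost with limma voom (adjusted p = 0.0712), without normal 1 (ratio 22.0, interval 5.95 to 183, adjusted p = 0.170), without normal 2 (0 normal counts, at least 15.5-fold, adjusted p = 0.0744), and without tumor 5 or 6 (adjusted p = 0.0669 and 0.0532). Of 22 transcription factors linked to small cell lung cancer, 10 rose, 1 fell and 11 did not pass, against 9 higher and 1 lower adjusted over the list alone. Id4 rose 7.15-fold, E2f3 4.90-fold, and Id3 was the member that fell (log2 fold change -2.19 ± 0.71). Id3 lost its call without normal 1 (-2.22), normal 2 (-2.20), tumor 3 (-2.02) or tumor 4 (-2.03), and without tumor 5, where it was -3.10, Id1 and Id2, named after their values were seen, fell as well. The list passed at adjusted p = 0.0167, with adjusted p = 0.383 with an estimated correlation and 0.0508 without tumor 5.

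Cell cycle and growth genes rose as groups. All 40 S phase genes and 47 of 49 G2/M genes were higher, with median log2 fold changes of 3.25 and 4.19, and none was lower. Mki67, the proliferation antigen, went from 46.2 ± 10.3 to 613 ± 128 CPM (3.73 ± 0.31, adjusted p = 0.000138). Rad51ap1 and Dtl, of DNA repair and replication licensing, rose 34.5-fold and 21.5-fold, and Ect2 and Hmmr, of cytokinesis and the spindle, 20.7-fold and 34.8-fold. All 30 Myc targets and ribosome biogenesis genes rose (median 2.24), among them the nucleolar proteins Nop56 at 13.8-fold and Nop58 at 9.55-fold. Of 22 nucleotide synthesis genes 18 rose (median 1.96), led by thymidine kinase Tk1 at 15.8-fold and the dUTPase gene Dut at 34.1-fold. Impdh1 and Prps2, of purine and phosphoribosyl pyrophosphate synthesis, fell by 0.97 and 0.69 on the log2 scale, the latter not past the threshold without normal 1 (-0.65) or normal 2 (-0.76). Camera with a preset correlation gave adjusted p = 1.1e-15, 2.19e-17, 5.68e-09 and 1.05e-05 for these 4 lists in order. With an estimated correlation these became adjusted p = 0.248, 0.248, 0.36 and 0.278.

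Among 24 p53 targets 13 fell, 4 rose and 7 did not pass (median -0.87, adjusted p = 0.022; adjusted p = 0.300 with an estimated correlation), and the list missed the threshold with the stricter filter (0.0538). Ccng1 was 3.61-fold and Trp53inp1 6.05-fold lower. The 4 that rose were Bax (1.21 ± 0.29), Aen (1.08 ± 0.27), Zmat3 (0.89 ± 0.22) and Mdm2 (0.55 ± 0.20). Without normal 1 or normal 2 none of the 4 passed, at 1.15 and 1.25 for Bax, 0.97 and 1.17 for Aen, 0.98 and 0.78 for Zmat3, and 0.59 and 0.48 for Mdm2, and without normal 1 the number that fell was 7. Mdm2 also missed the threshold without the filter (0.51) and without tumor 3 (0.50), tumor 4 (0.48) or tumor 5 (0.56).

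The histone deacetylase genes, the class of enzyme that the study targeted, moved in both directions. Hdac2 and Hdac3 rose from 72.6 ± 0.606 to 183 ± 10.6 CPM and from 36.6 ± 0.981 to 95.5 ± 5.78 CPM, log2 fold changes of 1.34 ± 0.14 and 1.38 ± 0.14 (adjusted p = 0.000348 and 0.000314). Hdac1 rose by 0.69 ± 0.22 (adjusted p = 0.0288), a call lost without normal 1 (0.67), normal 2 (0.68) or tumor 3 (0.68). Hdac9, a class IIa member, rose 29.6-fold, and Hdac6, a tubulin deacetylase, 2.51-fold. Hdac7 was 9.23-fold lower. Hdac5 fell by 0.86 on the log2 scale, and missed the threshold without normal 1 (-0.83). Hdac4 fell by 0.85 at adjusted p = 0.0496, and missed it without normal 1 (-0.90), normal 2 (-0.82), tumor 3 (-0.67), tumor 4 (-0.78) or tumor 6 (-0.85), and also with RLE factors (-0.80), total counts (-0.83), upper quartile scaling (-0.73), the stricter filter (-0.76) or the non-coding and histone genes removed (-0.77). The 11 genes as a list did not stand apart (5 higher, 3 lower, adjusted p = 0.317), and without normal 1 Hdac7 was the 1 gene that fell. Of 27 genes of chromatin repressor complexes 12 rose, 3 fell and 12 did not pass, with 11 and 3 adjusted over the list alone (adjusted p = 0.0173; adjusted p = 0.278 with an estimated correlation). Ezh2, the Polycomb methyltransferase, rose 9.58-fold and Dnmt1 3.56-fold. Ezh1, Mbd2 and Chd3 fell by 2.47, 1.34 and 2.05, with Chd3 not past the threshold without normal 1 (-2.04), normal 2 (-2.09), tumor 5 (-2.20) or tumor 6 (-1.76).

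Most antigen presentation genes were lower in the tumor samples. H2-K1, a class I heavy chain, went from 757 ± 22.9 to 90.2 ± 49.6 CPM (-3.07 ± 0.48, adjusted p = 0.00166), and B2m, its light chain, from 1206 ± 32.9 to 83.3 ± 42.1 CPM (-3.85 ± 0.44, adjusted p = 0.000468). H2-K1 shares sequence with other class I genes, so its counts are uncertain in how they are split. Of 18 class I genes 15 fell and none rose, with 16 lower adjusted over the list alone (median -3.10). Tapbp and Tap2, which load peptide, were 15.7-fold and 26.7-fold lower. Of 14 class II genes 12 fell, or 13 adjusted over the list alone (median -3.64), among them H2-DMa at 13.3-fold and Cd40 at 11.4-fold lower. Of 26 interferon response genes 17 fell and none rose (median -2.35), with the RNA sensors Ddx58 and Ifih1 20.5-fold and 12.3-fold lower. These 3 lists passed at adjusted p = 3.6e-05, 0.000739 and 3.6e-05, and had adjusted p = 0.343, 0.398 and 0.36 with an estimated correlation. Markers of other cell types were lower as well, with medians of -3.59 for T and NK cells, -3.15 for B and plasma cells, -2.56 for macrophages and -5.11 for endothelium. The class II list had a mean log2 CPM of 2.83, 0.77, 2.04 and 1.25 in tumors 3 to 6, and like the T and NK list (-0.36, -2.11, -1.17 and -1.46) and the B and plasma list (1.61, -1.29, -0.19 and -0.96) it was highest in tumor 3 and lowest in tumor 4. The class I list (5.11, 4.52, 4.66 and 4.04) and the macrophage list (3.42, 2.87, 2.68 and 2.05) were also highest in tumor 3 but lowest in tumor 6, and H2-K1 was highest in tumor 4, at 156 CPM. Counts of whole tissue do not separate tumor cells from other cells.

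Of 19 immune checkpoint genes 12 fell, 3 rose and 4 did not pass (median -2.37, adjusted p = 0.022; adjusted p = 0.383 with an estimated correlation). Cd274, the gene of PD-L1, was 7.96-fold lower at 3.08 ± 1.04 CPM against 24.5 ± 1.29 (adjusted p = 0.000598). The gene of the checkpoint protein VISTA, listed as 4632428N05Rik, was 11.9-fold lower, and the poliovirus receptor gene Pvr 11.3-fold lower. Cd276, the gene of B7-H3, rose from 4.62 ± 0.0928 to 40.1 ± 9.30 CPM (3.12 ± 0.29, adjusted p = 0.000223). Lag3 and Tnfrsf4 rose by 1.96 ± 0.51 and 1.31 ± 0.41, and missed the threshold without normal 1 (1.75 and 1.13) and without normal 2 (2.17 and 1.49).

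Most markers of T and NK cells, of B and plasma cells and of macrophages were lower in the tumor samples. Cd8a, of cytotoxic T cells, went from 3.94 ± 0.922 to 0.277 ± 0.157 CPM (-3.81 ± 0.67, adjusted p = 0.00276). Of 25 T and NK cell genes 21 fell, among them Zap70 at 12.0-fold and Cd3e at 25.1-fold lower, and 1 rose. That one was Foxp3 (1.00 ± 0.22), which overlaps Ccdc22 in the GRCm38 RefSeq annotation, so its reads are uncertain, and which missed the threshold without normal 1 (0.96) or normal 2 (1.01). Of 14 B and plasma cell genes 9 fell and none rose, with Cd79b 9.55-fold lower and Cd79a 10.1-fold lower, the latter not past the threshold without normal 2 (-2.59). Without normal 2, Cd79b and Cd22, the latter named after its values were seen, were the 2 B and plasma cell genes that fell. Without tumor 3 the list's median went from -3.15 to -3.87, Cd79b to -4.04 and Cd79a to -4.07. Of 24 macrophage and monocyte genes 16 fell, including Csf1r at 6.75-fold and Mrc1 at 7.28-fold, and 3 rose. These were the complement genes C1qb (1.33 ± 0.36) and C1qc (0.96 ± 0.29) and the scavenger receptor gene Msr1 (1.58 ± 0.50), none past the threshold without normal 1 (1.24, 0.86 and 1.65) or normal 2 (1.39, 1.03 and 1.48), nor Msr1 without tumor 3 (1.41). The 3 lists passed at adjusted p = 0.00013, 0.0119 and 0.00318, with adjusted p = 0.383, 0.489 and 0.417 with an estimated correlation. Of 13 neutrophil genes 5 fell, among them Csf3r and Cxcr2 at 12.4-fold and 9.76-fold lower, and the list did not pass with camera (adjusted p = 0.0973), except without tumor 3 (0.0296) or tumor 6 (0.0411) and with the stricter filter (0.0489). Without normal 1 or normal 2, Csf3r, Cxcr2 and Mmp9, the last named after its values were seen, were the 3 that fell, and the median of -0.87 became -1.47, -0.26 and -1.88 without normal 1, normal 2 and tumor 3.

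Most listed genes of the normal lung's cell types fell. The 8 lowest genes by the naming rule were Chia1 (521-fold), Cyp2f2 (319-fold), Scgb1a1 (264-fold), Tmem100 (243-fold), Cbr2 and Fmo1 (229-fold each), C7 (197-fold) and Myh7 (186-fold), where Scgb1a1 is the secretoglobin of club cells and Tmem100 an endothelial gene. Of the list members, 18 of 20 fell for alveolar type 2 cells, 14 of 15 for alveolar type 1, 12 of 16 for club and secretory cells (13 adjusted over the list alone), 18 of 20 for ciliated cells, 25 of 25 for endothelium, 20 of 25 for fibroblasts and matrix, and 9 of 11 for mesothelium (10 adjusted over the list alone). No member of these 7 lists rose. Their median log2 fold changes were -4.73, -5.47, -5.00, -4.09, -5.11, -3.47 and -4.10 in that order. The club and secretory median was -6.00 with DESeq2 and -5.97 with the stricter filter, each over 14 genes tested. Abca3, the surfactant lipid transporter, was 14.1-fold lower and Cd36 39.4-fold. Hopx and Rtkn2 were 28.5-fold and 15.5-fold lower, Aldh1a1 159-fold, the ciliary dyneins Dnah5 and Dnah9 16.9-fold and 21.5-fold, Eng and Kdr 58.4-fold and 71.3-fold, Mfap4 and Bgn 49.6-fold and 11.1-fold, and Krt19 and Upk3b 31.1-fold and 51.2-fold. Camera with a preset correlation gave adjusted p = 7.66e-05, 4.57e-05, 0.000262, 1.01e-05, 3.35e-10, 6.73e-06 and 0.00126. With an estimated correlation these were adjusted p = 0.383, 0.278, 0.278, 0.248, 0.248, 0.248 and 0.383.

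Of 18 smooth muscle and pericyte genes 15 fell and 1 rose (median -3.01, adjusted p = 0.000262; adjusted p = 0.248 with an estimated correlation). Mylk and Myh11 were 29.2-fold and 29.0-fold lower, whereas Rgs5, a pericyte regulator of G protein signalling, rose from 4.30 ± 0.0171 to 98.9 ± 31.3 CPM (4.53 ± 0.38, adjusted p = 0.000152). Of 7 erythroid genes 5 fell (adjusted p = 0.00948; adjusted p = 0.278 with an estimated correlation), with Alas2 11.7-fold and Slc4a1 27.9-fold lower. Of 9 Schwann cell genes 4 fell, led by Prx at 129-fold and Pmp22 at 38.3-fold, which other cells of the lung also express, and which were the 2 that fell without normal 1 or normal 2. That list passed at adjusted p = 0.0455, with adjusted p = 0.278 with an estimated correlation, and missed the threshold without normal 2 (0.0501), tumor 3 (0.0533), tumor 4 (0.0614) or tumor 5 (0.0501) and with the stricter filter (0.0880). Of 14 cardiac muscle genes 7 fell, or 6 adjusted over the list alone, and the list did not pass (adjusted p = 0.118) except without normal 1 (0.0162). Actc1 was at 31.3 CPM in normal 1 and 100 in normal 2, and Mybpc3 at 2.20 and 17.0. Their log2 fold changes were -4.34 and -4.31 without normal 1 and -2.67 and -1.37 without normal 2, where Actc1 was the 1 cardiac gene that fell and the list's median was -1.45, against -3.25 with all libraries and -4.02 without normal 1. Of 12 adipocyte genes 2 rose and 2 fell, against 0 and 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.375). Lipe, a lipase, was 3.98-fold lower. Fabp4, a fatty acid binding protein, rose by 1.67 ± 0.60 and Lep, the leptin gene, fell by 3.96 (adjusted p = 0.0442 and 0.0465). Fabp4 missed the threshold with limma voom (1.61) and without normal 1 (adjusted p = 0.230), normal 2 (2.29), tumor 3 (1.39) or tumor 6 (1.62). Lep missed it without the filter (-3.99), with upper quartile scaling (-3.85), and without normal 1 (-4.59), normal 2 (-2.85), tumor 3 (-3.54), tumor 4 (-3.79) or tumor 5 (-3.52), while without tumor 6, which left 2 tumor counts, its adjusted p was 0.00619. Ucp1, of brown fat, had 2 counts in normal lung and 148 in tumors, a ratio of 54.1 (95% interval 14.7 to 450, counting error only). It missed the threshold without normal 1 (ratio 26.2, interval 7.13 to 218, adjusted p = 0.124) and without normal 2 (0 normal counts, at least 18.6-fold, adjusted p = 0.0538). With limma voom 6 adipocyte genes fell.

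**Figure D2:**
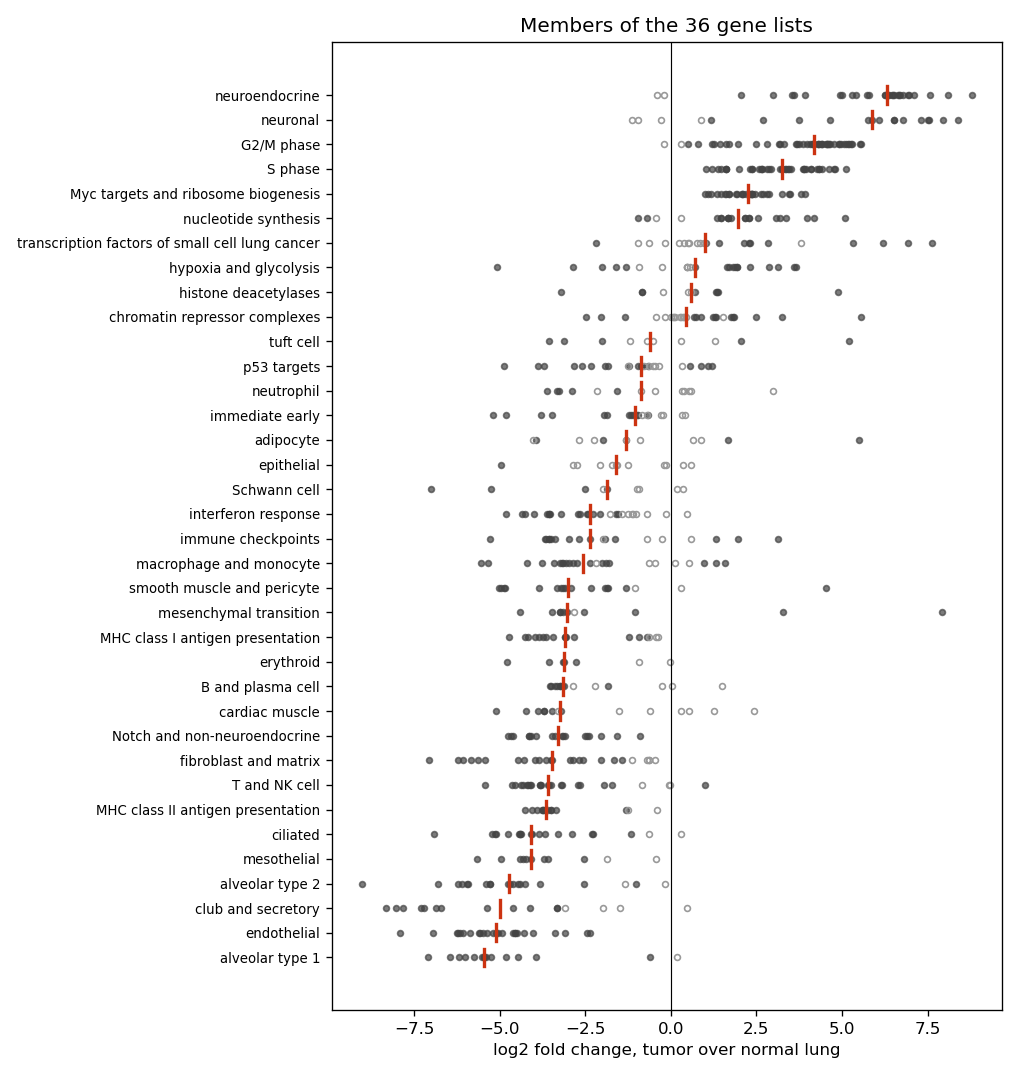
Log2 fold change, tumor over normal lung, of each member of the 36 gene lists, with filled points for genes past the threshold, open points for the others and a red bar at each list's median. The neuroendocrine list has the highest median, 6.31, and the alveolar type 1 list the lowest, -5.47.

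Of 18 immediate early genes 12 fell and none rose, with 13 lower adjusted over the list alone (median -1.05, adjusted p = 0.00282; adjusted p = 0.248 with an estimated correlation). Ier3 was 28.4-fold and Klf2 36.7-fold lower. Of 23 hypoxia and glycolysis genes 12 rose and 5 fell. The glycolytic enzymes Pgk1 and Tpi1 rose 3.67-fold and 3.84-fold, and the lactate dehydrogenase gene Ldhb and the angiogenic factor Vegfa were 34.1-fold and 7.21-fold lower. This list did not pass (adjusted p = 0.0824) except without tumor 3 (0.0475). Of 11 mesenchymal transition genes 8 fell, or 9 adjusted over the list alone, and 2 rose (median -3.04, adjusted p = 0.0167; adjusted p = 0.278 with an estimated correlation). Tgfbr2 and Sparc were 21.5-fold and 8.21-fold lower. Cdh2, the neuronal cadherin, rose 9.67-fold. Twist1, with 0 counts in normal lung and 108 in tumors, was at least 26.3-fold higher against a floor of 3 counts over the group. Its level was low, at 0.581, 0.157, 0.274 and 0.598 CPM in tumors 3 to 6. Of 12 epithelial genes only Krt19 passed the test (adjusted p of the list = 0.0740), whereas without tumor 4 11 of them fell and the list passed at 0.000457, with limma voom 8 fell, and without the filter at 0.0484.

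Among the 8 highest genes by the naming rule were Clca3b, Mir1949, Magel2, Dcx, Cadps, Snora74a and Stmn3. Clca3b, of the calcium-activated chloride channel regulators, had 2 counts in the normal libraries and 19273 in the tumors, a ratio of 7039 (95% interval 1948 to 58124, counting error only), and ran from 3.13 CPM in tumor 3 to 203 in tumor 4. Reads shared with its close relatives make its count uncertain, and its call was lost with limma voom (adjusted p = 0.172). The ratio was 3413 (945 to 28188) without normal 1 and 4046 (1120 to 33414) without tumor 4, and without normal 2, which left 0 normal counts, it was at least 2417-fold higher. Dcx and Stmn3, of neuronal microtubules, rose 334-fold and 249-fold, and Cadps, of dense granule release, 314-fold. These folds rested on few normal counts, with log2 fold changes of 7.41 for Dcx, 7.13 for Stmn3 and 7.33 for Cadps without normal 1, and 12.17 for Dcx and 9.94 for Stmn3 without normal 2. Cadps, without normal 2, had 2 normal counts, a ratio of 4398 (1217 to 36320, counting error only). That interval leaves out the 314-fold of all libraries. Magel2 rose by 8.59 ± 2.63 but stood at 217 CPM in tumor 3 and 1.41 in tumor 4. It missed the threshold with limma voom (9.25), without normal 1 (7.57) and without normal 2, which left 0 normal counts. Magel2 was then 2414-fold higher against the floor, by counting error only, and 385-fold higher over all libraries. Without tumor 3 its change was 6.87. Snora74a, a small nucleolar RNA, rose from 6.95 ± 3.80 to 1759 ± 258 CPM, and the row listed as Mir1949, which overlaps an annotated small nucleolar RNA in GRCm38, from 0.242 ± 0.314 to 167 ± 50.7 CPM. Without normal 2 the log2 fold change of Snora74a was 8.67. Mir1949 then had 2 normal counts, a ratio of 7945 (2199 to 65610, counting error only). It was 694-fold higher over all libraries, and its log2 fold change was 8.48 without normal 1. Both lack a poly(A) tail, as do the RNAs whose shares are given above.

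The tumors were not alike, and the labels divide them no further, so their values are given without a test. The treatment arm of each tumor is not known either, so treatment cannot be excluded as a source of their differences. Genes above 4-fold higher than in each other tumor, at 10 CPM or more, numbered 19, 118, 9 and 91 in tumors 3 to 6, and genes below each other tumor by as much numbered 16, 70, 0 and 31. The mean log2 CPM of the epithelial list was 6.16 in tumor 4, against 2.67, 2.55 and 2.07 in tumors 3, 5 and 6 and 6.14 and 6.15 in normal 1 and 2, although its member Krt19 was at 5.09 CPM in tumor 4 and 9.64 in tumor 3, against 185 ± 5.80 in normal lung. The alveolar type 2 list stood at 1.59 in tumor 6 and at 4.53, 4.53 and 4.99 in tumors 3, 4 and 5.

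**Figure D3:**
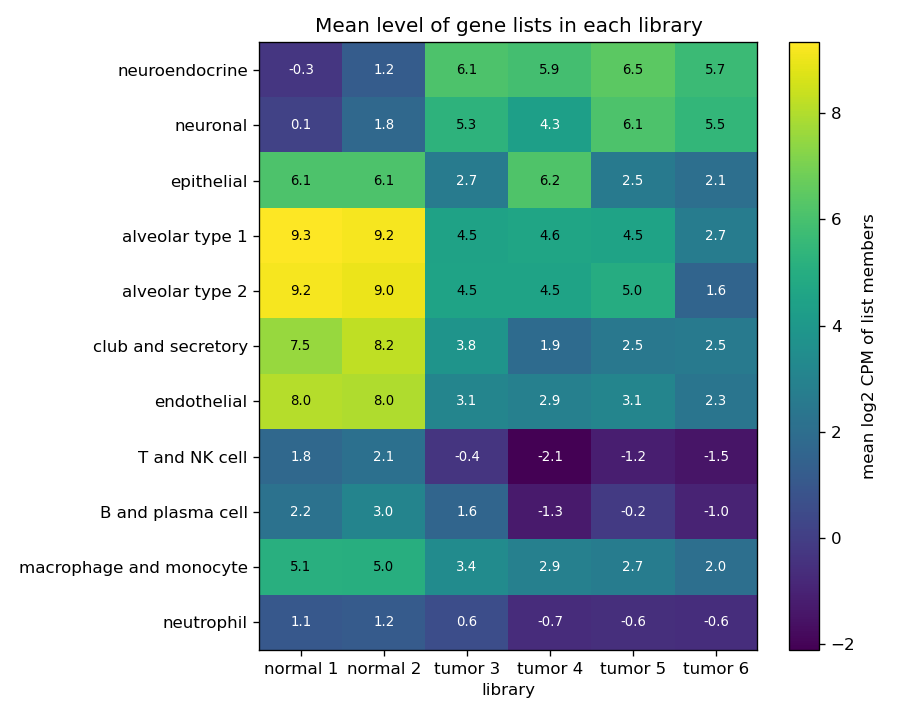
Mean log2 CPM of the members of 11 gene lists in each library, with the value written in each cell and the color scale at the right. Tumor 4 stands at 6.16 for the epithelial list, near the normal libraries, and tumor 6 at 1.59 for the alveolar type 2 list.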

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

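The tests of explanations, and the genes Epcam, Sftpc, Krt4, Krt13, Acta1 and Ckm, were chosen after the results were seen. Values are log2 CPM differences of 1 tumor from the mean of the other 3, for genes and lists in which 1 tumor stood apart from the other 3 by Dixon's criterion. These were 9 of 131 genes named by the rule and 4 of 36 lists, and chance alone meets the criterion in about 1 of 20 groups. Sftpc, Krt4 and Acta1 met it too, but were chosen after their values in tumor 6 were seen, so that chance rate does not apply to them.

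Tumor 6 carried genes of tissue that the labels do not name. Krt4, a keratin of stratified squamous epithelium, was 13.44 higher there (645 CPM, against 0.0298, 0.0393 and 0.0260), and Acta1, skeletal muscle actin, was 7.87 higher (321 CPM). Genes of both tissues whose values had not been looked at were also higher in tumor 6, by a median of 4.07 over 9 muscle genes and 3.00 over 5 squamous genes, so pieces of esophagus or another muscular, squamous-lined tissue may have been sampled with it, as a hypothesis. Of the 21 muscle and 15 squamous genes tested, 7 and 3 reached 1 CPM in both normal libraries and none was in another list, and the abundant Ckm and Krt13 stood at 146 and 555 CPM in tumor 6. No biological explanation was tested.

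Alveolar genes stood lower in tumor 6, by a difference of -3.09 for the alveolar type 2 list, -1.86 for the alveolar type 1 list, -6.09 for Sftpc and -3.13 for Chia1. Fmo1 (-1.40), Myh7 (-3.06), Ptgs1 (-1.53) and Ifih1 (-0.57) stood lower there as well. Other lists were also lower in tumor 6. Median differences were -1.43 for mesothelium (8 of 11 genes below every other tumor), -0.86 for macrophages (16 of 24), -0.69 for class I (13 of 18) and -0.59 for endothelium (16 of 25). They were -1.05 for B and plasma cells (7 of 14) and -0.71 for class II (3 of 14). Those lists were lower still in tumor 4, at -1.61 and -1.25. The epithelial median was -1.58 (7 of 12), against a mean that tumor 4 raised. It was -0.86 and -1.17 in tumors 3 and 5 as well. The medians were 0.03 for ciliated cells, 0.14 for smooth muscle, 0.28 for fibroblasts and 1.23 for adipocytes.

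The epithelial list stood 3.73 higher in tumor 4 than in the other tumors, with 11 of its 12 members above each of them and the exception of Krt19, at 5.09 CPM against 9.64 in tumor 3 and 185 in normal lung. Epcam was at 234 CPM in tumor 4, against 8.61, 7.23 and 2.17 in tumors 3, 5 and 6 and 72.9 ± 0.235 in normal lung. Residual normal epithelium would bring alveolar, club and ciliated transcripts at about the 321% of normal lung that Epcam reached, but their median was 2.84% over 71 genes (upper quartile 6.97%), which argues against it. Another state of the tumor cells may account for it, but 1 tumor of unknown treatment arm cannot decide this. Neuronal genes were also lower there (median difference -0.74), but so were B and plasma (-1.61), class II (-1.25) and T and NK (-0.97) lists. A lower level there was thus not particular to neuronal genes, of which 14 of 19 were below every other tumor and 0 above. It was not general either. Myc targets and ribosome biogenesis (0.54, 23 of 30 above every other tumor) and hypoxia and glycolysis (0.55, 14 of 23) were higher. The neuroendocrine list differed by -0.39, with 16 of 30 genes below every other tumor and 5 above. Chga and Calca were highest in tumor 4, at 162 and 293 CPM. In the same tumor Dcx differed by -3.44, Mbd2 by 0.76 and Pou2f3 by -1.09. The Pou2f3 value rested on 1 count there and 5 in each other tumor, near the floor.

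The neutrophil list was 1.20 higher in tumor 3 and Wwtr1 was 0.30 higher in tumor 5.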

How the results depend on the processing

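The removal of non-coding and histone genes was the 1 alternative chosen after the data were seen. All counts of genes past the threshold stayed within 1.5 times under the other scalings, filters and tools, and no list turned its direction. Leaving out single libraries gave 7651 to 12079 genes, of which 3373 (without normal 1) to 5912 were higher. The share of higher genes ran from 44.1% without normal 1 to 52.4% with upper quartile scaling. Upper quartile scaling raised the median log2 fold change of the same 18027 genes from 0.02 to 0.14. The median move per gene was 0.12 there, 0.10 without tumor 6, and under 0.1 in size in every other alternative (0.05 with DESeq2, -0.03 without a filter). Of 135 genes checked, 104 kept their direction and their side of the threshold in every alternative that gave a value. Krt4 and Epcam, neither past the threshold with all libraries, turned. The Krt4 log2 fold change was 9.81, at most 10.23 (without tumor 5), and -2.37 without tumor 6 (adjusted p = 0.0176). That of Epcam was -0.21, but 0.16, 0.17 and 0.25 without tumors 3, 5 and 6, and -3.60 without tumor 4 (adjusted p = 0.0028). The self-test and the 2 normal libraries limit calls of small changes.

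With an estimated correlation no list passed. The adjusted p was 0.248 for the Notch, S phase, G2/M, ciliated, endothelial, fibroblast, smooth muscle and immediate early lists, 0.278 for the neuroendocrine, nucleotide, chromatin, alveolar type 1, club, Schwann, erythroid and mesenchymal lists, and 0.300 for p53 targets. It was 0.343 for class I, 0.36 for Myc targets and interferon, 0.383 for the neuronal, checkpoint, T and NK, alveolar type 2, mesothelial and transcription factor lists, 0.398 for class II, 0.417 for macrophages and 0.489 for B cells. The Schwann cell estimate, -0.0787, lay below the preset 0.01, yet camera's unadjusted p went from 0.0366 to 0.0956. For fibroblasts, with an estimate of 0.0165, it went from 1.31e-06 to 0.0103. Losses of calls in this setting therefore did not come from larger correlations alone. With fry, the histone deacetylase (0.00537), neutrophil (0.0107) and tuft (0.0423) lists passed. The stricter filter ended the call of p53 targets (0.0538) and Schwann cells (0.0880) and made neutrophils pass (0.0489), and without a filter the epithelial list passed (0.0484), on other sets of genes tested. Fry, which gave 0.000991 for p53 targets, tests whether a list moves one way and does not compare it with other genes. With camera, over the other scalings, filters, left-out libraries and the estimated correlation, adjusted p ranged from 0.0113 to 0.300 for p53 targets, 0.258 to 0.417 for histone deacetylases and 0.175 to 0.607 for tuft cells. Over single libraries left out, adjusted p ranged from 0.0162 to 0.370 for cardiac muscle, 0.000457 to 0.132 for epithelial, 0.0475 to 0.136 for hypoxia and glycolysis, 0.0296 to 0.159 for neutrophil, 0.0195 to 0.0614 for Schwann cell and 0.00961 to 0.0508 for transcription factors. Except for the filters, the cause was not tested.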

Other observations

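All tests in this part were chosen after the results were seen. Small nucleolar RNA and histone genes were far higher in tumors. Of 106 small nucleolar RNA genes 101 rose and none fell, with a median log2 fold change of 4.49 (quartiles 3.70 and 5.23), and 65 of 73 histone genes rose (median 4.69). Of 264 microRNA genes 102 rose and 31 fell (median 1.35, quartiles -0.31 and 2.56). Rn45s took 7.82%, 6.93%, 1.16% and 2.66% of the counts in tumors 3 to 6 and 0.164% and 0.320% in normal 1 and 2, whereas Rmrp varied less between the tumors, at 2.29%, 2.54%, 2.06% and 3.13%.

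As a hypothesis, the tumor libraries may hold more RNA without a poly(A) tail. Ribosome biogenesis of the tumor cells as the whole cause is argued against by the spliceosomal, Cajal body and telomerase RNAs, which serve other functions and rose in 12 of 12 cases with a median of 6.09 (quartiles 2.84 and 6.81). More tailless RNA kept in the tumor libraries needs the snoRNA genes to rise, which they did by 4.49, but the design places tissue and library together, so it cannot be told apart from a higher level in the tumor tissue. Without the non-coding and histone rows 11317 genes passed the test, so the count of calls does not rest on them.

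Normal 2 carried more of the tumor genes than normal 1. Over 152 genes at least 5 log2 units higher in tumors and at 50 CPM or more there, 149 were higher in normal 2, at a median of 2.21% of the tumor mean against 0.812% in normal 1. Over 203 genes at least 5 log2 units lower in tumors, the tumors held a median of 1.99%, 1.64%, 2.25% and 0.975% of the normal level in tumors 3 to 6. Both sets of genes were chosen on these data for their large differences. The small size of the shares follows from that choice, so only differences between libraries are informative.

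Xist was at 1691 CPM in tumor 3 and at 0.0393, 0.300 and 0.180 CPM in tumors 4 to 6, with 1.95 and 2.60 in normal 1 and 2. The Y-linked Ddx3y was at 0 CPM in tumor 3, 138 and 103 in normal 1 and 2, and 47.0, 92.9 and 87.3 in tumors 4 to 6. Kdm5d and Eif2s3y were also at 0 CPM in tumor 3, and Uty at 0.0447. These are the levels of a female in tumor 3 and of males in the other libraries. Sex was not a term in the test, and what sets tumor 3 apart cannot be told apart from it.

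Several marker lists stood higher in tumor 3 than the mean of the other 3 tumors. The median log2 difference was 2.09 for B and plasma cells, 1.44 for MHC class II, 0.95 for neutrophils and 0.73 for both macrophages and the interferon response. It was 1.78 for cardiac muscle, 1.64 for adipocytes, 1.46 for club cells, 1.17 for mesothelium and 1.06 for erythroid genes, against 0.19 for endothelium and -0.26 for fibroblasts. In tumor 3, 12 of 14 B and plasma cell genes, 13 of 14 class II genes, 18 of 25 T and NK genes and 10 of 11 mesothelial genes were above every other tumor. Fewer were so for neutrophils (7 of 13), cardiac muscle (7 of 14), adipocytes (6 of 12) and erythroid genes (4 of 7). Adipocyte genes were also higher in tumor 6, by a median of 1.23.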
